A study of Homo sapiens with 16 samples.

How the data were processed

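Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in HEK293T cells, an established human embryonic kidney line, with paired-end reads of 150 bp per the labels. The 16 samples fall into 8 groups of 2 labelled replicates. HDGF was immunoprecipitated from cells given a control depletion and from cells kept for 24 h without glucose. INTS13 was immunoprecipitated from cells given a control depletion, from cells depleted of HDGF with a pool of small interfering RNAs for 72 h, and from cells kept for 24 h without glucose. The other 6 samples are inputs of the same 3 conditions. Per the labels, the HDGF antibody was the same in both HDGF groups (Proteintech). The INTS13 antibody came from Bethyl Laboratories in the control and HDGF-depletion groups and from Proteintech in the starvation group, so antibody and treatment cannot be told apart in the comparison of INTS13 in starvation.

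The authors deposited 1 peak list per ChIP group, and 5 lists were used here. Per the submitters' processing notes the tools were FastQC, Trimmomatic, Bowtie, Picard and MACS2 and the build was hg38. Versions and settings are not given in the sources used here, apart from the value 0.05 in the deposited peak names. How the replicates were combined and how the inputs entered peak calling are likewise not given in the sources used here. Each peak in the deposited files has an integer score, a fold enrichment over background at the summit, −log10 p and −log10 q values, and a summit position, all of them the authors' values. Folds and −log10 q values were used only to describe, rank or filter peaks within a list. Input samples were not analysed here.

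In each list every fold had a single p-value. Of the 601 distinct pairs of fold and p over the 5 lists, 600 followed a Poisson distribution with a single mean per list, with reads at the summit rounded down after scaling and errors of at most 0.00016 in −log10 p, and 1 did not. That mean gives the background in reads per position. Before the scaling that the values of the starvation lists imply, it was 6.69 for HDGF control, 9.84 for HDGF starvation, 6.40 for INTS13 control, 4.20 for INTS13 after HDGF depletion and 15.2 for INTS13 starvation. After scaling it was 7.41 in both starvation lists, and the other lists were not scaled. The highest summit held 400 reads in every list despite these different backgrounds. This value may thus be a ceiling, at which the folds of the strongest peaks are cut off, and it does not measure depth. The backgrounds are the only measure of depth used here, and no other read total was used. A local background or input coverage would give 1 fold several p-values, and none of the folds had more than 1, so regions with more DNA or better mapping are not corrected for.

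Genes came from a RefSeq table of the same assembly, with 20037 protein-coding genes on chromosomes 1 to 22, X and Y. The table used here has no strand, so a start site could not be told from an end, and a gene was counted as holding a peak when a summit lay within 1 kb of either end of the gene (a boundary peak). This replaces the promoter window planned before the data were examined. Matching on the GC content of promoters, also planned, was not possible without a genome sequence and was replaced by matching on the type of gene, on 5 classes of gene length and on 5 classes of regional peak density. Where a summit lay in the windows of several genes, each of those genes was counted, and for named genes the gene with the nearest boundary was taken. Peaks on alternate or unplaced sequences were left out of all comparisons.

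Peaks overlapped when they shared at least 1 base. Kept, lost and gained describe presence in the control and treated lists: kept genes had a boundary peak in both, lost genes in the control list only and gained genes in the treated list only. With a single list per group there was no test between conditions and no p-value. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only. Observed overlaps were set beside 100 random placements of the peaks within their chromosomes and, as a description chosen after the data were seen, beside 100 sets in which each peak was displaced by 20 to 200 kb, which keeps the regional density of peaks. Expected gene overlaps were computed within 5 Mb bins. Retention of INTS13 peaks was compared within 10 strength classes of INTS13 control peaks ranked by −log10 p and averaged. The 95% interval of this average is a normal approximation and not an exact interval. It treats peaks as independent although they cluster in the genome, so it is likely too narrow.

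The named genes were chosen by a rule written before the data were examined: for each of the 3 comparisons the 8 kept and 8 lost protein-coding genes with the highest control −log10 q and the 8 gained genes with the highest treated −log10 q, all members of the Integrator and HDGF family lists and all snRNA genes with a peak, and up to 4 members of each other list. Some genes that the rule names are not reported here. There were 21 lists, also fixed beforehand: Integrator subunits, the HDGF family, snRNA genes, small RNA genes of RNA polymerase III, replication-dependent histones, immediate early genes, integrated stress and glucose starvation genes, glycolysis, oxidative phosphorylation, autophagy and lysosome, AMPK and mTOR, cholesterol biosynthesis, ribosomal proteins, RNA polymerase II pausing and termination, cilia, zinc finger and NAB partners, cell cycle, and markers of liver, blood, muscle, and neurons and glia. In all, 1 list member (NDUFA4) was missing from the table of genes. The number of members with a boundary peak was placed among 10000 random lists of the same size matched as above, and its percentile is a description of these lists. With 105 such percentiles, 26 lay at or above 97.5 and 3 at or below 2.5, where chance gives about 2.6 at each end.

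Overlap and gene assignment were tested on simulated data. All planted overlaps with INTS13 control peaks were found (100%), as were 200 of 200 planted boundary genes, and lists displaced independently of each other gave observed over expected overlaps of 1.01 to 1.02. The alternatives were boundary windows of 500 and 2500 bp, any base of the peak in the window, shared bases of at least 50% of both peaks, summits within 250 bp, peaks with −log10 q of at least 10, lists of equal length, and, added after the data were seen, the strongest 15000 peaks and the genome without chromosomes 1, 13, 22 and X. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1 were used.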

Results

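ChIP-seq was used in HEK293T cells to map INTS13, a subunit of the Integrator complex that cleaves nascent RNA at snRNA genes and at paused RNA polymerase II, and HDGF, a chromatin-binding protein with a PWWP domain. The series asked whether INTS13 moves on the genome when cells are starved or when HDGF moves or is depleted. Each of the 5 ChIP groups had 2 labelled replicates and a single deposited peak list, so no value below has a replicate error. The lists held 106674 peaks for HDGF in control cells, 68138 for HDGF in starved cells, 31233 for INTS13 in control cells, 105994 for INTS13 after HDGF depletion and 15639 for INTS13 in starved cells. Within each protein the longer list had the lower background in reads. Before scaling it was 4.20, 6.40 and 15.2 for INTS13 in depleted, control and starved cells and 6.69 and 9.84 for HDGF in control and starved cells. After scaling it was 7.41 in both starvation lists. Peaks with a −log10 q of at least 10 numbered 683, 548, 749, 495 and 420 in the same order of lists as above.

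Chromosomes 1, 13, 22 and X held 46.7% of HDGF control peaks, 46.5% of HDGF starvation peaks, 79.4% of INTS13 control peaks, 49.7% of INTS13 peaks after HDGF depletion and 65.9% of INTS13 starvation peaks, against 18.5% of protein-coding genes. Chromosome X alone held 2.62% and 3.05% of the HDGF control and starvation peaks, below its 4.23% of genes. The strongest interval of all, on chromosome 16 from 46388569 to 46392035 and 77302 bp from the nearest annotated gene, was present in all 5 lists. Its summit held the maximum of 400 reads in each, and in INTS13 starvation it tied with an interval on chromosome 1 (fold 23.2). Of the 100 strongest HDGF control peaks, 92 overlapped one of the 100 strongest INTS13 control peaks and 84 one of the 100 strongest HDGF starvation peaks. The same 100 peaks overlapped any peak at 100 in HDGF starvation and 100 in INTS13 control. They did so at 97 in INTS13 after HDGF depletion and 96 in INTS13 starvation, so the strongest signal was common to all lists. Summits of the 3 lists from control-depleted and HDGF-depleted cells lay at gene boundaries a little more often than displaced peaks did, at 1.13 times for HDGF control, 1.21 times for INTS13 control and 1.12 times for INTS13 after HDGF depletion. In starved cells the ratios were 1.60 for HDGF and 2.53 for INTS13. Among peaks with a −log10 q of at least 10 the ratio was 6.49 for INTS13 control, 5.27 after HDGF depletion and 10.1 in starvation, and 2.13 and 2.15 for HDGF in control and starved cells. With a window of 500 bp the HDGF control ratio was 0.967 (interval 0.928 to 1.01).

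**Figure D1:**
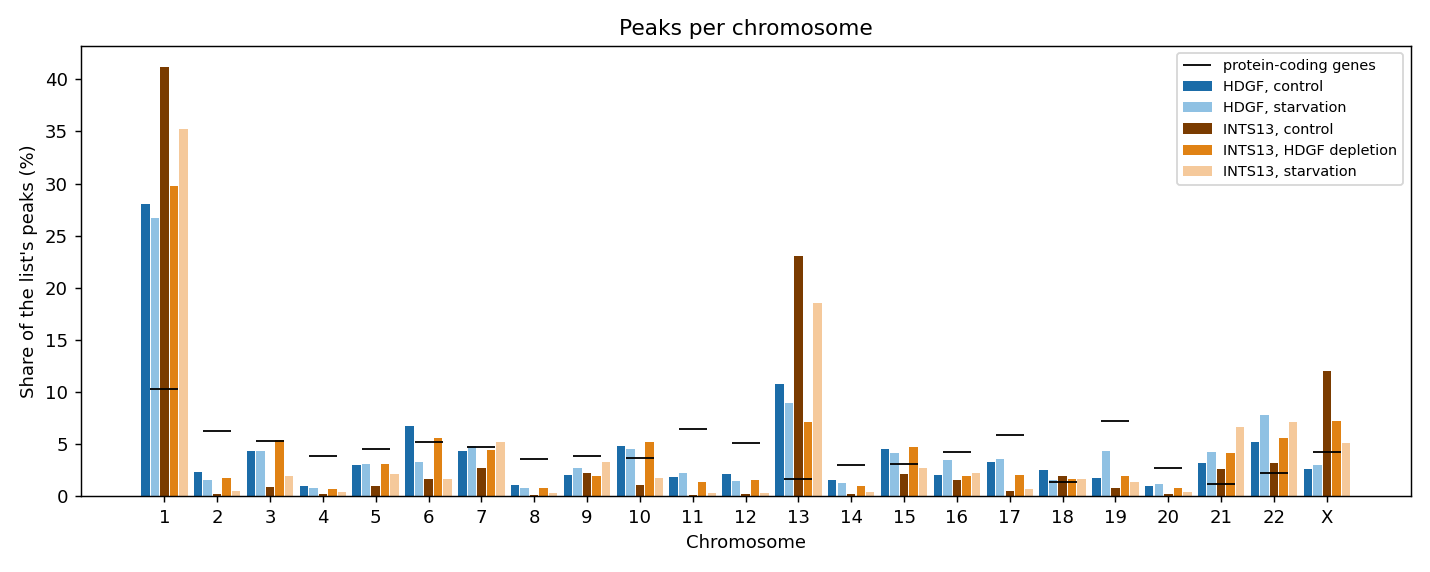
Share of each list's peaks on chromosomes 1 to 22 and X in percent (bars, 1 per peak list), with the share of protein-coding genes as black marks. Chromosomes 1, 13, 18, 21 and 22 lie above their share of genes in all 5 lists.

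**Figure D2:**
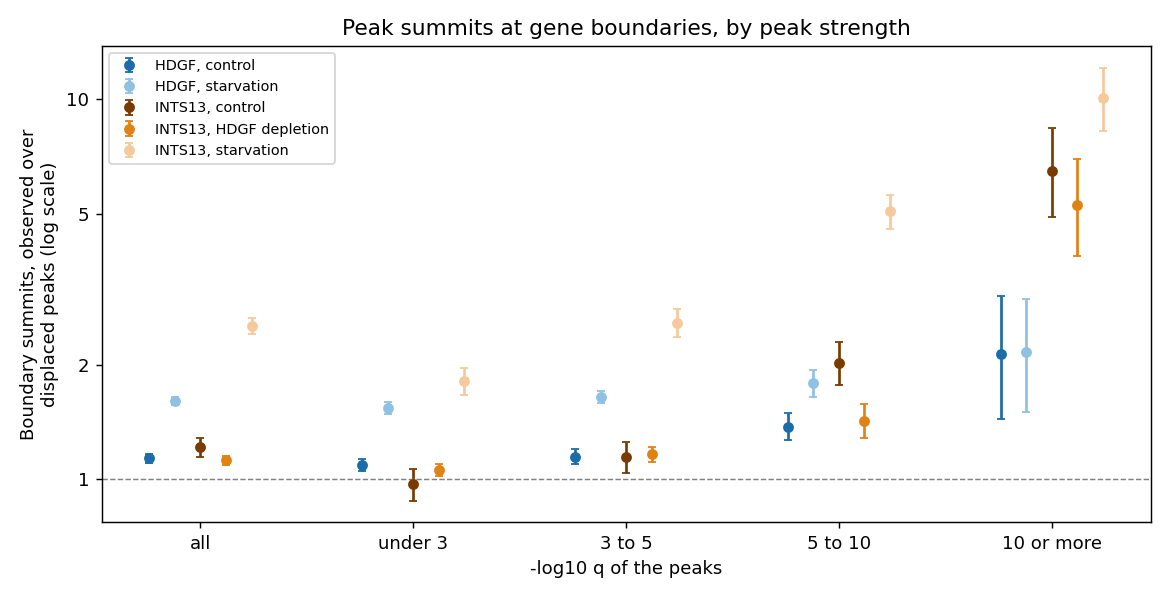
Peak summits within 1 kb of a protein-coding gene's ends divided by the mean of 100 sets of displaced peaks (log scale), for all peaks and by −log10 q, with 95% exact binomial intervals of the observed count (points and bars). Weak INTS13 control peaks with −log10 q under 3 sit at 0.967, and the INTS13 peaks of starved cells with −log10 q of at least 10 sit at 10.1.

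The first comparison asked whether HDGF lies at other genes after glucose starvation. Ribosomal protein genes formed the group most often marked by HDGF in control cells, with 41 of 55 members, including RPS6, RPS2, RPS27 and RPL10A. In starvation 30 of the 55 had a boundary peak: 26 were kept, 15 were lost, among them RPL27, RPL5 and RPL14, and 4 were gained, among them RPLP2, RPS19 and RPL13. Genes of the integrated stress response and of glucose starvation were at 18 of 38 in control cells and 17 of 38 in starved cells. There HDGF was kept at 12, including STC2 (fold 4.29 in the control list), ATF4 (4.03), the stress-response transcription factor, XBP1 (3.90) and DDIT4 (3.77). It was lost at 6, including PHGDH, CTH, HERPUD1 and MTHFD2, and gained at SESN2 (fold 4.42 in the starvation list), an mTORC1 inhibitor induced by stress, SHMT2 (3.34), TRIB3 (2.98), GDF15 (2.81) and WARS1 (2.36).

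Of 3868 protein-coding genes with an HDGF boundary peak in control cells, 2029 were kept in starvation (52.5%, interval 50.9 to 54.0), against 1490 expected within 5 Mb bins, 1839 were lost and 2310 were gained. Kept means a peak at either end of the gene: 1666 of the 2029 had a summit at the same end in both lists (82.1%, interval 80.4 to 83.8), and at 1167 the peaks overlapped (57.5%, interval 55.3 to 59.7). At STC2, RPS6, PRKAA2, MCL1 and CDKN1A the control and starvation summits lay at opposite ends. The kept genes with the highest control −log10 q were RBM34, C1orf35, RPS6, H3-3A, which encodes histone H3.3, MAZ, LIN9, CNIH4 and RAB42, with folds of 5.20 (RAB42) to 5.73 (RBM34). The lost genes included GPRIN2, PSEN2, a presenilin of the gamma-secretase complex, CSNK1E, HOXB3, CCDC28B, LAMA4 and EIF4EBP2, a repressor of translation, with control folds of 4.29 (EIF4EBP2) to 5.60 (GPRIN2 and PSEN2). The gained genes were NBPF1, ARF1, TMEM63A, PRSS38, SESN2, YPEL1, DEGS1 and LOC124904970, with starvation folds of 4.33 (DEGS1) to 6.03 (NBPF1). NBPF1 belongs to a family of near-identical copies and is uncertain. ARF1 and the kept gene C1orf35 lie side by side on chromosome 1, and the starvation interval from 228092668 to 228102766 covers the facing ends of both. The control interval from 228094517 to 228102063 covers them too, so ARF1 counts as gained because the summit lay nearer to it in starvation, and not because HDGF was absent in control cells. The class also changed for GPRIN2, PSEN2, CSNK1E, CCDC28B, NBPF1, TMEM63A, SESN2, YPEL1 and DEGS1 when any base of the peak in the window counted, and for these and HOXB3, LAMA4 and PRSS38 with a window of 2500 bp, so their calls as lost or gained depend on where the summit lay.

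HDGF peaks at genes of energy metabolism were counted in both lists, of which the control list is the longer, while the share of all protein-coding genes with an HDGF boundary peak was 19.3% in control and 21.7% in starved cells. Glycolysis genes were at 11 of 25 in control (interval 24.4 to 65.1%) and 7 of 25 in starvation (12.1 to 49.4%), with PKM, TPI1, ENO1 and PGAM1 kept, ALDOA, SLC16A1, ENO2 and SLC2A1, the main glucose transporter, lost, and SLC16A3 gained. Oxidative phosphorylation genes were at 15 and 11 of 32 (29.1 to 65.3% and 18.6 to 53.2%), with ATP5PO, CYC1, COX5A and ATP5F1B kept and UQCRQ, NDUFS3, SDHB and SDHA lost. Cholesterol genes were at 13 and 10 of 25, with SREBF1, FASN, MVK and FDPS kept and HSD17B7, INSIG1, SCD and SQLE lost. Cell cycle genes were at 12 and 7 of 37, with MCM2, MCM3, E2F1 and MCM7 lost and MCM5, CDC25A and CDKN1A kept. AMPK and mTOR genes were at 9 and 8 of 20, with PRKAA2 and TSC2 kept, and immediate early genes at 11 and 8 of 34, with JUN, BTG2, ATF3 and MCL1 kept and SRF lost. Autophagy and lysosome genes were at 9 and 8 of 41, with SQSTM1 kept, MAP1LC3B and GABARAP lost and CTSD gained.

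Transcription factor genes of the zinc finger and NAB list were at 10 and 8 of 22, with MAZ, THAP11 and ZMYND8 kept and YY1 lost. Among Integrator subunits HDGF was at 5 of 19 in control cells and 7 of 19 in starved cells. It was kept at INTS5, INTS14, NABP2 and BRAT1, lost at INIP, and gained at INTS1, INTS11 and INTS15. Of the HDGF family, HDGF itself had a peak in both lists (fold 4.03 in control and 3.25 in starvation, with the strongest peaks at opposite ends of the gene and weaker ones at the same end), and HDGFL2 and HDGFL3 were gained. Genes of polymerase II pausing and termination were at 6 of 33 in both lists, with MEPCE and SUPT5H kept, CDK9 and HEXIM1 lost and SYMPK gained. Cilia genes were at 6 and 3 of 40, with IFT27 kept and IFT46 lost, small RNA genes of polymerase III at 4 and 2 of 18 (RNY5 and RNY4 kept), and histone genes at 1 (H4C11) and 0 of 50. The snRNA genes were at 2 of 19 in both lists, with RNU11 kept (by peaks that did not overlap), RNU5A-1 lost and RNU7-1 gained. Marker genes of other tissues were at 0 and 3 of 16 for liver (APOA1, APOA2 and APOC3), 1 and 0 of 20 for blood (CD2), 4 and 6 of 17 for muscle (ACTN2, CKM, ACTA1 and MYOG kept) and 0 and 1 of 14 for neurons and glia.

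Of 106674 HDGF control peaks, 22387 overlapped an HDGF starvation peak (21.0%, interval 20.7 to 21.2), against 4.22% for random placement and 16.2% for displaced peaks. The starvation list is the shorter, and the share was 26.5% in lists of equal length. Of the HDGF starvation peaks 34.9% overlapped an HDGF control peak, against 26.8% for displaced peaks. With both lists taken at 68138 peaks, 1583 of 2740 control genes were kept (57.8%), 1157 were lost and 2756 were gained. Among peaks with a −log10 q of at least 10, 5 genes were kept, 24 lost and 35 gained.

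INTS13 and HDGF were compared with each other in control cells. INTS13 lay at more snRNA genes than HDGF: INTS13 had a boundary peak at 12 of 19 snRNA genes and HDGF at 2 of 19 (RNU5A-1 and RNU11), or 13 and 7 of 19 with a window of 2500 bp. The INTS13 peaks were strongest at RNU11 (fold 9.19, peak on chromosome 1 from 28648477 to 28649322) and RNU2-2 (8.11, chromosome 11 from 62840921 to 62841879), followed by RNU4-2 (5.41), RNU5D-1 (5.27), RNU5E-1 (5.13), RNU5F-1 (5.13), RNU5A-1 (4.19), RNU5B-1 (4.19), RNU12 (4.05), RNU4ATAC (4.05), RNVU1-7 (3.78) and RNU7-1 (2.70). The snRNA count lay above nearly all random lists (percentile 100 after rounding), while that of HDGF lay at percentile 9.12. The snRNA genes belong to families of near-identical copies, and a gene without a peak is uncertain. Outside snRNA genes the proteins often shared genes, with 598 of 956 INTS13 genes holding HDGF as well (62.6%, interval 59.4 to 65.6), 1.36 times the 439 expected within 5 Mb bins. A shared gene had a summit of each protein at either end, and how many had both at the same end was not counted. At MCOLN1, CTH, ATG3 and PKM the strongest peaks of the proteins lay at opposite ends, and at DDIT4 they overlapped. Of 31233 INTS13 control peaks, 14066 overlapped an HDGF peak (45.0%, interval 44.5 to 45.6), against 8.20% for random placement and 39.9% for displaced peaks. The share was 31.9% in lists of equal length, 20.5% by summits within 250 bp and 9.61% with at least 50% of both peaks shared. Of the peaks with a −log10 q of at least 10, 386 INTS13 peaks overlapped HDGF and 3 genes held both. At this level 84.6% of INTS13 control peaks and 60.2% of HDGF control peaks lay outside genes and away from their boundaries. The strongest of these intervals were present in all 5 lists, so shared strong peaks do not tell joint binding from signal common to all lists.

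**Figure D3:**
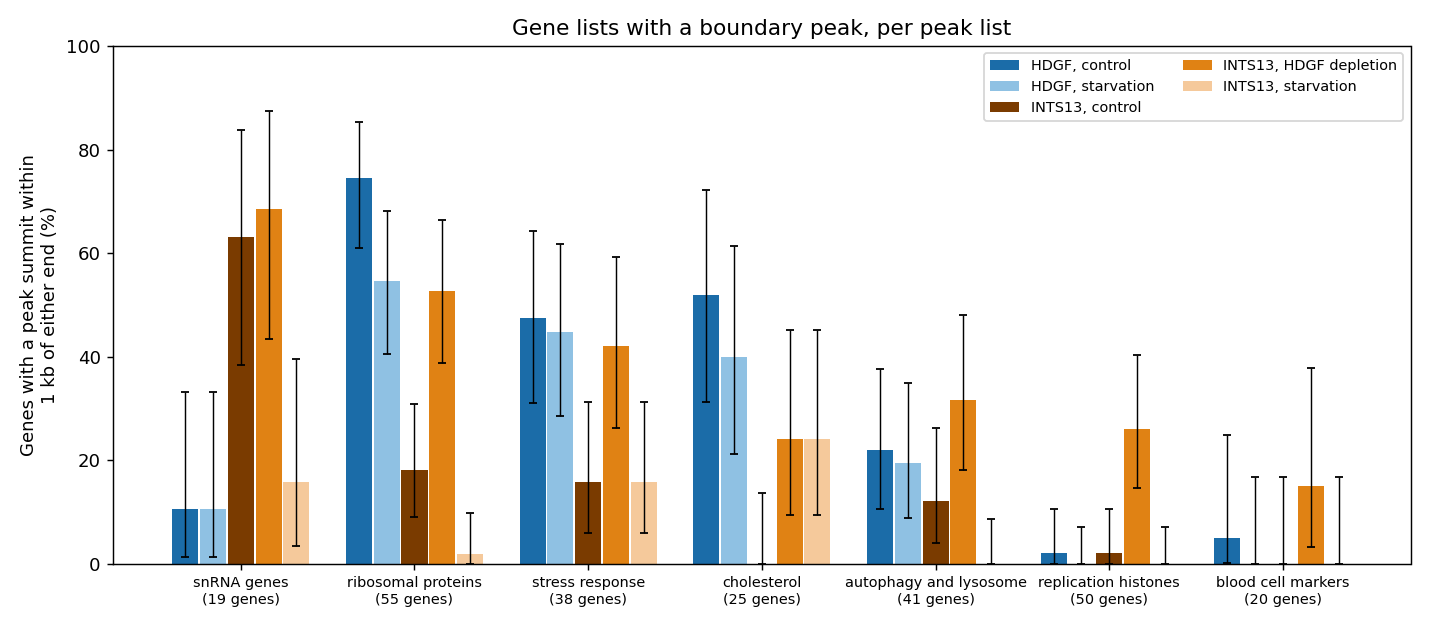
Percent of the members of 7 gene lists with a peak summit within 1 kb of either gene end in each of the 5 peak lists (bars), with exact 95% binomial intervals. INTS13 control and depletion bars reach 63.2% and 68.4% of snRNA genes, and the starvation bar 15.8%.

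HDGF depletion was used to ask whether INTS13 moves without HDGF. INTS13 stayed at snRNA genes: all 12 that had a peak in control cells had one after depletion, with folds of 9.24 at RNU11, 8.08 at RNU2-2, 5.97 at RNU5F-1, 4.62 at RNVU1-7, 3.66 at RNU5D-1, 3.46 at RNU4-2 and 3.08 at RNU5E-1 in the depletion list, and RNU1-2 was gained. Among the 15000 strongest peaks of each list 11 snRNA genes had one in control cells and 7 after depletion. INTS13 was also kept at all 5 autophagy and lysosome genes it marked in control cells. These were LAMP1, a lysosomal membrane protein (fold 9.46 in the control list, peak on chromosome 13 from 113296933 to 113297268), HEXA, a lysosomal hydrolase (6.62), ATG3 (4.32), the lysosomal channel MCOLN1 (3.92) and CTSA (3.51). A further 8 were gained, including ATG12, ATP6V0D1, ATG14 and ATG7, which made 13 of 41. Replication-dependent histone genes, which are expressed in S phase, had an INTS13 peak at 1 of 50 in control cells (H1-4) and at 13 of 50 after depletion, with H2AC17 (3.85), H2BC17 (3.85), H2BC14 (3.66) and H4C3 (3.46) among the 12 gained. H2AC17 and H2BC17 share 1 peak, on chromosome 6 from 27893444 to 27893828, and so do H2AC6 and H2BC4, from 26124332 to 26124613. Over all protein-coding genes the share with an INTS13 peak rose from 4.77% to 19.1% in this longer list, and among the 15000 strongest peaks histone genes were at 0 of 50 in control cells and 2 of 50 after depletion.

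Of 956 genes with an INTS13 boundary peak in control cells, 777 were kept after HDGF depletion (81.3%, interval 78.7 to 83.7; 503 expected within 5 Mb bins), 179 were lost and 3051 were gained. Of the kept genes 706 had a summit at the same end in both lists (90.9%) and 573 had overlapping peaks (73.7%). The depletion list was the longest INTS13 list and had the lowest background. With both lists taken at 31233 peaks, 554 genes were kept, 402 lost and 844 gained. The kept genes with the highest control −log10 q were LAMP1, GET4, TAF12, WDR74, TM2D1, SPANXB1, HEXA and KDM5C, an H3K4 demethylase. The TAF12 peak is the one over RNU11 and the WDR74 peak the one over RNU2-2. The lost genes were MAN2C1, GAGE12B, NBPF1, NUP88, a nucleoporin, EIF3B, MRPL39, PRR12 and TERF1, a telomere-binding protein, with control folds of 4.32 (TERF1) to 5.13 (MAN2C1). The gained genes were IP6K1, MTREX, an RNA helicase of the nuclear exosome, AP5Z1, RPS6KB1, CEBPA, KAT5, PSG5 and TASOR, with folds of 5.20 (CEBPA) to 5.58 (MTREX). SPANXB1, GAGE12B, NBPF1 and PSG5 have near-identical copies and are uncertain.

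All other gene lists had more INTS13 genes after depletion, in the list with the most INTS13 peaks. Ribosomal protein genes went from 10 to 29 of 55, with RPL5, RPS2, RPS6 and RPL3 kept, RPL7A lost and RPL32 and RPL10 among the gained. Stress and starvation genes went from 6 to 16 of 38, with SESN2, ATF4, DDIT4 and CTH kept and STC2 and XBP1 gained. Glycolysis genes went from 2 (ALDOA and PKM) to 8 of 25, oxidative phosphorylation genes from 4 to 11 of 32 (CYC1 and NDUFA9 kept), and AMPK and mTOR genes from 2 (TSC1 and PRKAG2) to 7 of 20, with RPS6KB1 gained. Cholesterol genes went from 0 to 6 of 25 (FDPS and INSIG1 among them), immediate early genes from 3 to 8 of 34 (JUND gained and MYC lost), and cell cycle genes from 3 to 9 of 37, with CCND3, CDC25C and MCM5 kept. Zinc finger and NAB partner genes went from 1 (MAZ) to 9 of 22, cilia genes from 1 (IFT27) to 4 of 40, and polymerase II pausing and termination genes from 4 to 5 of 33, with CPSF2 and POLR2A kept and HEXIM1 and CSTF2 lost. Integrator subunits went from 0 to 2 of 19 (INTS5 and INTS14), the HDGF family from 0 to 2 of 5 (HDGF and HDGFL3) and small RNA genes of polymerase III from 1 (RNY3) to 3 of 18. Markers of other tissues went from 1 to 4 of 16 for liver (CYP2E1 gained), 0 to 3 of 20 for blood (CD4 gained), 1 to 7 of 17 for muscle (ACTA1 gained) and 1 to 2 of 14 for neurons and glia (SLC17A7 gained).

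INTS13 sites with HDGF were found again after HDGF depletion more often than sites without it. Of the 14066 INTS13 control peaks that overlapped an HDGF control peak, 9525 were found again (67.7%, interval 66.9 to 68.5), and of the 17167 that did not, 6199 (36.1%, interval 35.4 to 36.8). Averaged over 10 classes of INTS13 peak strength the difference was 26.4 percentage points (interval 25.3 to 27.5), and 17.2 points when the depletion list was displaced. It was 8.70 points when summits within 250 bp counted as overlap. Of all 31233 INTS13 control peaks, 15724 were found again (50.3%, interval 49.8 to 50.9), against 6.64% for random placement and 32.2% for displaced peaks. This share was 32.7% in lists of equal length. Genes with INTS13 after depletion held HDGF of control cells at 1813 of 3828 (47.4%), 1.32 times the number expected within 5 Mb bins. In control cells this ratio was 1.36. INTS13 peaks after depletion overlapped HDGF control peaks at 1.14 times the displaced value, against 1.13 times for INTS13 control peaks. The excess of INTS13 at HDGF sites of control cells was thus about the same after HDGF depletion.

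**Figure D4:**
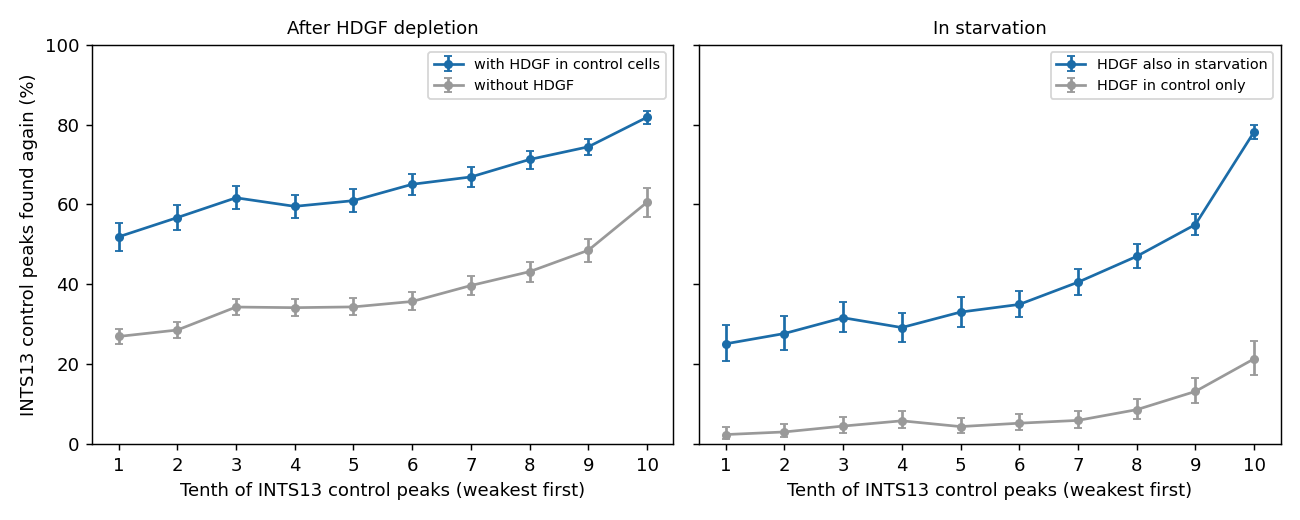
Percent of INTS13 control peaks that overlap an INTS13 peak after HDGF depletion (left) or in starvation (right), over 10 strength classes from weakest to strongest, with exact 95% binomial intervals. Peaks with HDGF (left) and peaks that kept HDGF in starvation (right) lie above the others in all 10 classes.

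INTS13 in starved cells was compared with INTS13 in control cells to ask whether starvation moves it, and the antibody differed between these groups. INTS13 had a boundary peak at 3 of 19 snRNA genes in starved cells, against 12 in control cells. RNU11 (fold 4.28 in the starvation list), RNU2-2 (4.05) and RNU12 (3.07) were kept, and RNU4-2, RNU5A-1, RNU5B-1, RNU5D-1, RNU5E-1, RNU5F-1, RNU4ATAC, RNVU1-7 and RNU7-1 were lost. At RNU12 the starvation peak (42614504 to 42614703) did not overlap the control peak (42615217 to 42615787). None of the 41 autophagy and lysosome genes had an INTS13 peak, and LAMP1, HEXA, ATG3, MCOLN1 and CTSA were all lost. Ribosomal protein genes went from 10 of 55 to 1 of 55 (RPL10, gained), with RPL5, RPS2, RPS6 and RPL3 among the lost. Cholesterol genes went the other way, from 0 to 6 of 25, among them SREBF2, the transcription factor of the pathway (fold 3.93), FASN (3.01), FDPS (3.01) and INSIG1 (2.66).

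Of the 956 control genes, 512 were kept in starvation (53.6%, interval 50.3 to 56.8; 268 expected within 5 Mb bins), 444 were lost and 833 were gained. Of the kept genes 444 had a summit at the same end in both lists (86.7%) and 362 had overlapping peaks (70.7%), and at DDIT4 and DNAJC8 the summits lay at opposite ends. With both lists taken at 15639 peaks, 368 of 594 control genes were kept (62.0%), 226 were lost and 977 were gained. The kept genes were GET4, TAF12, WDR74, TM2D1, SPANXB1, KDM5C, DNAJC8 and MPI, with control folds of 6.35 (MPI) to 9.19 (GET4). The lost genes were LAMP1, HEXA, UBE2Q1, CLCN6, a chloride transporter of endosomes and lysosomes, SIRT4, the apoptosis effector BAX, SUMF1, which activates lysosomal sulfatases, and WASHC2A, with control folds of 5.27 (BAX) to 9.46 (LAMP1). The SIRT4 peak is the one over RNU4-2. The gained genes were SMARCD2, a SWI/SNF subunit (fold 8.79 in the starvation list, peak on chromosome 17 from 63842496 to 63842955), TAF4, a TFIID subunit (7.52), RUFY1 (6.25), the histone methyltransferase KMT5B (5.61), IRAK1 (5.50), SMOC1 (5.50), CEBPA (5.32) and SMURF2 (5.32).

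Stress and starvation genes had an INTS13 peak at 6 of 38 in both lists. SESN2 and DDIT4 were kept, ATF4, CTH, SARS1 and TXNIP were lost, and XBP1 (4.28), SLC7A5 (3.36), CEBPB (3.18) and STC2 (3.13) were gained. Cell cycle genes went from 3 to 5 of 37, with CCND3, CDC25C and MCM5 kept and CDC25A and CCNE1 gained. Polymerase II pausing and termination genes went from 4 to 5 of 33, with POLR2A, the largest subunit of the polymerase, and CPSF2 kept, HEXIM1 and CSTF2 lost and NELFCD, MEPCE and CPSF1 gained. Immediate early genes went from 3 to 5 of 34 (BTG2 and JUN kept, MYC lost, SRF and JUND gained), AMPK and mTOR genes from 2 to 3 of 20 (TSC1 lost, PRKAA2 gained) and glycolysis genes from 2 to 3 of 25 (ALDOA and PKM kept, PFKL gained). Oxidative phosphorylation genes went from 4 to 3 of 32 (CYC1 and ATP5PO kept), zinc finger and NAB partners from 1 to 2 of 22 (MAZ kept, ZNF592 gained), and Integrator subunits from 0 to 2 of 19 (INTS1 and INTS14). The HDGF family went from 0 to 1 of 5 (HDGFL3), cilia genes from 1 to 1 of 40 (IFT27 lost, TMEM216 gained), histone genes from 1 to 0 of 50 and small RNA genes of polymerase III from 1 to 0 of 18. Markers of other tissues were at 0 of 16 for liver, 0 of 20 for blood, 3 of 17 for muscle (ACTN2 kept, ACTA1 and TNNT2 gained) and 1 of 14 for neurons and glia.

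INTS13 peaks of starved cells overlapped HDGF peaks of starved cells at 11265 of 15639 (72.0%, interval 71.3 to 72.7), against 5.28% for random placement and 34.3% for displaced peaks. The share was 45.4% with HDGF cut to the same number of peaks, 41.4% with summits within 250 bp and 27.0% with at least 50% of both peaks shared. INTS13 starvation peaks that overlapped a control INTS13 peak overlapped HDGF of starved cells at 5271 of 6355 (82.9%, interval 82.0 to 83.9), 1.74 times the displaced value. INTS13 peaks outside the control INTS13 peaks numbered 9284. Of these, 5994 overlapped HDGF of starved cells (64.6%, interval 63.6 to 65.5), a smaller share but 2.56 times the displaced value. This share was 36.8% in lists of equal length (3963 of 10769), 39.0% by summits within 250 bp (4504 of 11550), 23.5% with at least 50% of both peaks shared (2985 of 12729) and 32.6% at a −log10 q of at least 10 (44 of 135). HDGF of control cells overlapped 2203 of the same 9284 peaks (23.7%, interval 22.9 to 24.6), 0.904 times the displaced value. This lower value is partly built in. The 9284 peaks were chosen for not overlapping INTS13 control peaks, 45.0% of which overlapped HDGF of control cells, and the displaced sets were not filtered in this way. Signal common to ChIPs of starved cells, such as open chromatin, was not tested and could give the same contrast, and the INTS13 antibody differed as well. Of the 833 genes where INTS13 was gained, HDGF was gained at 223 (26.8%, 160 expected within 5 Mb bins), kept at 281 (209 expected), lost at 96 (88.5 expected) and absent from both HDGF lists at 233 (376 expected). In starved cells 881 of 1345 INTS13 genes held HDGF (65.5%, interval 62.9 to 68.0), 1.36 times the number expected within 5 Mb bins. Here too the summit of each protein could lie at either end of the gene.

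INTS13 sites were found again in starvation more often where HDGF was also found again. Among INTS13 control peaks that overlapped an HDGF control peak, 4389 of the 9092 that also overlapped HDGF in starvation kept INTS13 (48.3%, interval 47.2 to 49.3). Of the 4974 that did not overlap HDGF in starvation, 356 kept INTS13 (7.16%, interval 6.46 to 7.91). Averaged over the 10 strength classes the difference was 32.8 percentage points (interval 31.5 to 34.1), and 10.6 points when the INTS13 starvation list was displaced. It was 13.7 points when summits within 250 bp counted as overlap. Of all INTS13 control peaks, 6924 were found again in starvation (22.2%, interval 21.7 to 22.6), against 1.62% for random placement and 13.3% for displaced peaks. The starvation list is the shorter, and the share was 32.6% in lists of equal length. Of the INTS13 starvation peaks 40.6% overlapped an INTS13 control peak, against 23.7% for displaced peaks.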

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

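A few peaks lay on alternate or unplaced sequences of the assembly, which no comparison used: 23 in HDGF control, 17 in HDGF starvation, 16 in INTS13 control, 30 in INTS13 after HDGF depletion and 7 in INTS13 starvation. They are given because they are signal in data outside the comparisons and number more than a count of 0 allows (3), a bound that any handful of peaks passes and that says nothing about binding there. Their highest fold was 5.27, in INTS13 control.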

How the results depend on the processing

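No paired analysis was possible because each group has a single peak list with no values per replicate, and for the same reason leaving out a replicate was not run. Values without chromosomes 1, 13, 22 and X and at the 15000 strongest peaks, and all boundary ratios with their alternatives, were added after the data were seen. Of 125 recomputed values, 39 stayed close, 85 moved and 1 fell on the other side of 1. Counts move by construction with the number of peaks, the window or the overlap required, and for the ratios and differences the cause was not tested. Counts of kept, lost, gained and shared protein-coding genes with any base of the peak in the window all stayed within 1.5 times. Of 72 named gene entries, 55 kept their class with a 500 bp window, 53 with 2500 bp, 60 with any base in the window, 40 at a −log10 q of at least 10 and 68 at the 15000 strongest peaks. In the HDGF comparison 12 of 24 kept their class with 500 bp, 10 with 2500 bp, 13 with any base and 9 at a −log10 q of at least 10. For INTS13 these were 21, 19, 23 and 11 of 24 after depletion and 22, 24, 24 and 20 in starvation. The number of snRNA genes with INTS13 ran from 11 to 13 in control, 7 to 14 after depletion and 2 to 3 in starvation over both other windows, any base and the 15000 strongest peaks. The number with HDGF in control ran from 0 to 7 over the same settings, with 1 at 500 bp and 7 at 2500 bp.

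With a 500 bp window 829 genes kept HDGF in starvation, 469 kept INTS13 after HDGF depletion, 1901 gained it, and 287 held both proteins in control cells. The boundary ratio fell below 1 for HDGF control, to 0.967 with an interval that reaches 1 (0.928 to 1.01), and was 1.51 for HDGF starvation, 1.44 for INTS13 control and 3.51 for INTS13 starvation. With 2500 bp HDGF was kept at 4162 and lost at 2978 genes in starvation, INTS13 was kept at 1315 and gained at 4929 after depletion and kept at 776 and lost at 714 in starvation, and 1185 genes held both. The ratios were 1.36 for HDGF control, 1.53 for HDGF starvation, 1.11 for INTS13 control and 1.72 for INTS13 starvation.

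At a −log10 q of at least 10 HDGF was kept at 5, lost at 24 and gained at 35 genes in starvation, INTS13 at 28, 38 and 23 after depletion and at 32, 34 and 75 in starvation, and 3 genes held both. INTS13 overlapped HDGF at 386 control and 269 starvation peaks, 280 INTS13 peaks were found again after depletion and 332 in starvation, 245 HDGF peaks were found again, and 44 new INTS13 starvation peaks overlapped HDGF. The retention differences were 13.7 points after depletion and 43.4 in starvation. The boundary ratios were 2.13 (HDGF control), 2.15 (HDGF starvation), 6.49 (INTS13 control), 5.27 (INTS13 after depletion) and 10.1 (INTS13 starvation). At the 15000 strongest peaks the first 4 were 1.32, 1.77, 1.48 and 1.39.

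In lists of equal length HDGF was lost at 1157 genes in starvation, INTS13 was lost at 402 and gained at 844 after depletion and lost at 226 in starvation, and 374 genes held both. INTS13 starvation peaks overlapped HDGF at 7094, 10205 INTS13 peaks were found again after depletion, 3963 new INTS13 starvation peaks overlapped HDGF, and the retention difference in starvation was 39.2 points.

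With at least 50% of both peaks shared, INTS13 overlapped HDGF at 3000 control and 4223 starvation peaks, 6598 INTS13 peaks were found again after depletion and 2910 in starvation, 6009 HDGF peaks were found again, 2985 new INTS13 starvation peaks overlapped HDGF, and the retention differences were 8.20 and 16.98 points. With summits within 250 bp the first 5 of these counts were 6413, 6478, 10317, 4100 and 11764, with differences of 8.70 and 13.7 points.

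Without chromosomes 1, 13, 22 and X HDGF was kept at 1242 genes, INTS13 was kept at 332 and lost at 105 after depletion and kept at 229 and lost at 208 in starvation, and 234 genes held both. INTS13 overlapped HDGF at 2134 control and 3459 starvation peaks, 2518 INTS13 peaks were found again after depletion and 1457 in starvation, 7466 HDGF peaks were found again, 2365 new INTS13 starvation peaks overlapped HDGF, and the starvation retention difference was 34.9 points. The boundary ratios were 1.18 for HDGF control, 1.57 for INTS13 control and 3.15 for INTS13 starvation.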

Other observations

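The tests below were chosen after the results were seen, except the displaced lists for retention, whose bounds were set beforehand.

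Lysosomal genes were among the strong INTS13 peaks obtained with the Bethyl Laboratories antibody. With peaks of −log10 q of at least 5, a threshold chosen after the values were seen, LAMP1, HEXA, ATG3 and MCOLN1 had one in control cells (4 of 41 list members) and LAMP1, HEXA, ATG3 and CTSA had one after HDGF depletion. With all peaks the control count lay at percentile 98.3 of random lists matched on gene length and regional peak density. It was 1 of 105 such percentiles, so taken by itself a chance choice of genes cannot be ruled out. The count after HDGF depletion, with the same antibody, lay at percentile 99.3. Of the 105 percentiles 26 lay in the top 2.5%, where chance gives about 2.6, ribosomal protein genes in INTS13 control (100 after rounding) among them. High percentiles were thus not particular to lysosomal genes, and the random lists were not matched on expression. CLCN6, SUMF1 and WASHC2A, outside the list, act in endosomes or on lysosomal enzymes, and were singled out after their values were seen. A hypothesis is that INTS13, or another protein this antibody recognises, may sit near lysosomal genes, which ChIP with a second antibody in control cells, or after INTS13 depletion, would test. The starvation list, made with another antibody, had 0 of 41, so starvation and antibody cannot be told apart here.

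HDGF summits of control cells showed no excess right at gene boundaries, at 0.967 times the displaced value within 500 bp (interval 0.928 to 1.01), and 1.36 times within 2500 bp. INTS13 starvation summits had the opposite order, 3.51 within 500 bp and 1.72 within 2500 bp. The cell cycle genes CCND3, CDC25C and MCM5 had an INTS13 peak of −log10 q of at least 5 in control and starved cells, and CCNE1 and CDC25A in starved cells, which put 5 of 37 cell cycle genes in the starvation list.

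All 5 lists were dense in largely the same regions, apart from chromosome X, and the densest 63 of 631 bins of 5 Mb held 57.5% (HDGF control) to 88.6% (INTS13 control) of peaks. Gene density is too weak to account for this, since its highest rank correlation with a list was 0.577, below the lowest between lists of different proteins (0.708, difference 0.13, bootstrap interval 0.06 to 0.21). Extra copies of these regions, read against a single genome-wide background, may account for many weak peaks. On chromosomes 1, 13, 22 and X INTS13 control summits lay at gene boundaries 1.07 times as often as displaced peaks (interval 0.989 to 1.15), against 1.57 times elsewhere, but in starved cells the ratios on the same chromosomes were 1.53 for HDGF (interval 1.47 to 1.60) and 2.002 for INTS13 (interval 1.85 to 2.16). Copy number and binding cannot be told apart without input coverage or copy number, which were not analysed here.

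INTS13 peaks with HDGF were found again more often. With overlap of at least 1 base, regional peak density and peak width alone gave at most 18.5 of the 26.4 points after HDGF depletion and at most 11.7 of the 32.8 points in starvation, over 100 displaced lists. They thus do not account for all of either difference under that definition, but gave most of the difference after depletion. By summits within 250 bp both differences were smaller, and no displaced lists were run for that definition. A local property of the sites, such as open chromatin or ease of mapping, was not tested and stays open. For starvation the INTS13 antibody differed as well.

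Starvation lists lay closer to gene boundaries for both proteins, although HDGF boundary peaks with a −log10 q of at least 10 (29 in control and 34 in starvation) were too few to tell, with ratios of 2.13 (interval 1.44 to 3.03) and 2.15 (interval 1.504 to 2.97), and the INTS13 intervals at that level also met (4.90 to 8.39 in control and 8.25 to 12.1 in starvation). List length does not account for it: at 15000 peaks each the ratio was 1.77 for HDGF starvation against 1.32 in control, and 2.57 for INTS13 starvation against 1.48. A different antibody cannot account for the HDGF part, where the antibody was the same and the ratio was 1.60 against 1.13, but for INTS13 antibody and starvation cannot be told apart. The higher background in reads of the starvation lists and the control depletion, which the starvation labels do not mention, also coincide with the groups. Starvation itself stays among the open explanations, and the single list per group leaves no replicate check.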
